A study of Homo sapiens with 12 samples.

How the data were processed

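The series holds 12 RNA sequencing libraries of the human glioblastoma line U251, 3 in each of 4 groups: wild-type or TRPV2 knockdown cells, each under DMSO or piperlongumine, collected after 48 h. Libraries were made from total RNA with a TruSeq version 2 kit, which selects polyadenylated RNA and does not mark the strand, so genes that overlap on opposite strands cannot be told apart. Sequencing was on a HiSeq 2500. The submitters' processing notes name STAR 2.4.1d, Bowtie2 2.2.5, Partek and the genome build hg38, with no role or order. They do not state how reads were assigned to genes, how values were normalized or which genes were kept.

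The deposited table gives a log2 normalized expression value for each of 13588 genes in each library, and names genes by symbol only. That the scale is log2 was read from the values. Every library had the same maximum of 15.8752 and a median between 3.54 and 3.55, so the authors' values share a near-common distribution across libraries, and a change shared by most genes cannot appear in them. The values carry no counts. Low values lie at a regular spacing, which gave an estimate of the reads behind a normalized value of 1, from 13.9 to 52.1 over the libraries. The normalization bends that spacing, so whole reads were not recovered and no counting interval was computed. Genes with exactly tied values, which grow in number as reads become fewer, were counted in each library.

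Values were returned to the linear scale, 1 was added, and log2 was taken again. Fold changes on this scale understate the changes of low genes. Genes with a linear value of 1 or more in at least 3 libraries were tested, which left out 8 genes and kept 13580. All 12 libraries entered 1 linear model with a term for each group, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust). The contrasts were piperlongumine against DMSO in wild-type cells and in knockdown cells, knockdown against wild-type cells under DMSO and under piperlongumine, and the interaction, which is the piperlongumine response of knockdown cells minus that of wild-type cells. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and errors beside log2 changes are the standard errors (SE) of limma. The labels number the replicates but do not say whether they were separate cultures or what a number shares. If they were not separate cultures, the p-values measure only the spread between these samples. Libraries of the same number deviated together from their group means, with correlations of 0.168 to 0.361 for piperlongumine in wild-type cells, 0.288 to 0.449 for knockdown under DMSO and 0.217 to 0.342 under piperlongumine. In these 3 comparisons the numbers were taken to pair the libraries, from the values and not from the labels. For piperlongumine in knockdown cells the correlations were 0.454, -0.066 and 0.215. The model and the permutation tests of slopes do not use the pairing, and values with a replicate block are given where they change a call.

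Before the data were examined, 30 gene lists with 623 genes were fixed, of which 517 genes were tested. They cover stress responses, cell division, metabolism, matrix and adhesion, calcium, protein turnover, signs of RNA quality, markers of other cells and the neighbours of TRPV2. The 25 lists with at least 5 tested members were tested against all other genes with camera at a preset correlation between genes of 0.01. They were tested again with the correlation estimated for each list, and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. Of the 5 lists not tested, all markers of other cells, the tested members numbered 2 for neurons, 1 for oligodendrocytes, 0 for leukocytes and microglia, 4 for endothelium and 2 for epithelium. The statistical plan, the comparisons and the rule for named genes were fixed at the same time.

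The rule named TRPV2 first, which is not analysed here. In each pairwise comparison it then named the 6 largest called rises and the 6 largest called falls among genes with a mean value of at least 12.0 on the linear scale, the median of tested genes, and no overlap between the libraries of both groups. It added the 3 members with the smallest p of up to 6 lists that passed camera, except lists of RNA quality, and 4 genes in each direction for the interaction. The result of 1 gene that the rule took is not reported here. The 884 genes with clone-based names were tested but treated as having no name; the pattern that recognises such names was widened after the first ranking.

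Genes were matched to GENCODE 29 by symbol. 12351 matched by current symbol and 4 by an older one, 29 had several matches and 1204 none. The share of G and C bases (GC content) and the length of the longest transcript were taken from that annotation for 12347 of the tested genes. A correction for GC content and length, added after the data were seen, removed from each library a smooth trend (loess, span 0.4) of each gene's deviation from its mean, first on GC content and then on log2 length. Positions are on hg38. On simulated data with 200 changed genes, limma found 93.6%, 91.7%, 90.3% and 86.8% of changes of log2 1 in the 4 pairwise comparisons, in the order above. Of changes of log2 0.50 it found 45%, 38.8%, 41.1% and 30.6%, with 5 to 8 false calls. Noise was drawn independently for each gene and with the same spread in every comparison. These shares therefore differ by the draw alone, and deviations shared by many genes of a library were not simulated. A simulated GC trend alone gave 5160 calls without the correction and 159 with it, when 175 genes were truly changed.

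Alternatives were a replicate block, only the compared groups in the model, quantile normalization, other filters and pseudocounts, a test against a log2 change of 1 (treat), and each library left out in turn. Added after the data were seen were the GC and length correction, alone and with the replicate block, the log2 values as deposited, and a fit without the 3 libraries with most tied values. Tests that need counts were not run, since the values are not counts. Slopes of expression on GC content were compared by two-sided exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.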

Results

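Gene expression was measured by RNA sequencing in U251 cells, a human glioblastoma line. The cells were wild type or carried a CRISPR interference knockdown of TRPV2, in which an inactive Cas9 held at a gene represses its transcription. TRPV2 encodes a calcium-permeable cation channel of the cell membrane and of endosomes. Each kind of cell received DMSO, the solvent, or piperlongumine, an alkaloid of long pepper that reacts with thiols, for 48 h, with 3 libraries in each of the 4 groups. Total reads are not given. The spacing of low values put a normalized value of 1 at about 13.9 reads in wild-type DMSO replicate 1, 19.7 in wild-type DMSO replicate 3, 19.6 in wild-type piperlongumine replicate 1 and 32.7 to 52.1 in the other 9 libraries. Genes with exactly tied values numbered 720 to 1315 in 9 libraries, but 3133 in wild-type DMSO replicate 1, 2189 in wild-type DMSO replicate 3 and 2650 in wild-type piperlongumine replicate 1. Pearson correlations between replicates, across genes, were 0.959 to 0.986. The first principal component held 56.9% of the variance and set wild-type cells under piperlongumine, with a mean of 49.8, apart from wild-type DMSO at -27.2, knockdown DMSO at -14.3 and knockdown piperlongumine at -8.25. TRPV2 itself was not analysed here, so the knockdown was not checked through its own message. Its 9 tested neighbours on chromosome 17 had a median log2 difference of -0.041 between knockdown and wild-type cells under DMSO (camera adjusted p 0.987).

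The first comparison asked what piperlongumine does to wild-type glioblastoma cells. By list medians, calcium and immediate early response genes, targets of the adhesion-sensitive regulators YAP and TAZ and mitochondrially encoded messages shifted upward against other genes, and genes of mitosis and of the proteasome downward, at a preset correlation between genes. With an estimated correlation none of these lists passed (adjusted p 0.725 for each). SPRY4, an inhibitor of growth factor receptor signalling, rose by log2 2.42 ± 0.30 (SE, n = 3 per group, adjusted p 4.0e-05), or 5.36-fold (hg38, chromosome 5, 142310427 to 142326455). MT-ND1, a mitochondrially encoded subunit of respiratory complex I, rose by log2 2.59 ± 0.19 (adjusted p 6.6e-07). TTK, a kinase of the mitotic checkpoint, fell by 1.29 ± 0.11 on the log2 scale (adjusted p 7.7e-07), and PSMA1, a subunit of the proteasome core, fell by 0.96 ± 0.082 (adjusted p 7.7e-07).

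With 3 libraries in each group, 8614 of 13580 genes were called, 63.4%, of which 3987 were higher and 4627 lower under piperlongumine, and 1594 changed at least 2-fold. Among genes with a name, at or above the median abundance, without overlap between the groups, the largest rises were in RN7SK, MT-ND1, MT-CYB, MT-ND5, SPRY4 and PKD1P1. MT-CYB, which encodes cytochrome b, rose by log2 2.50 ± 0.20, and MT-ND5 by 2.45 ± 0.20 (adjusted p 1.2e-06 and 1.1e-06). RN7SK, the 7SK RNA that restrains transcription elongation, rose by log2 2.90 ± 0.83 (adjusted p 0.0138), and PKD1P1 by 2.36 ± 0.15 (adjusted p 1.5e-07). Within a group RN7SK varied, at 13.95 in wild-type piperlongumine replicate 1 and 15.8752 in replicates 2 and 3. How evenly the selection of polyadenylated RNA kept RN7SK was not tested. RN7SK held the common maximum of the normalized values, 15.8752, in 5 of the 12 libraries, so the size of its changes is bounded by the normalization. A gene with a clone-based name and no match in the annotation held that maximum in the other 7, which included the 3 wild-type DMSO libraries and wild-type piperlongumine replicate 1, and stood at 8.69 to 12.35 in these 5. PKD1P1 is a pseudogene close in sequence to PKD1, so reads cannot be assigned to it with certainty. The largest falls among the same genes were in PI15, a secreted peptidase inhibitor, at log2 -2.36 ± 0.36 (adjusted p 0.00028), and NDUFA5, a nuclear-encoded subunit of complex I, at -1.95 ± 0.15 (adjusted p 4.1e-07). TBL1XR1, a corepressor component, fell by 1.90, TWF1, an actin-binding protein, by 1.84, SNRPF, a spliceosome core protein, by 1.80 and UPRT, a relative of a pyrimidine salvage enzyme, by 1.73 on the log2 scale. The rule required that these 12 genes have no overlap between both groups' libraries.

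Of the 25 tested lists, 7 passed camera in wild-type cells. Of 20 calcium and immediate early response genes, 16 rose, with a median of log2 0.97 (adjusted p 0.00039). SPRY4, the early transcription regulators IER2 (log2 1.48) and NR4A2 (0.83, or 1.65 in the values as deposited, with no pseudocount) were the members with the smallest p. Of 13 mitochondrial messages 9 rose (median 1.29, adjusted p 0.00039) and MT-ND6, the message on the opposite strand, fell by 0.55, but stood at 0.019 after correction for GC content and length. Of 25 genes of G2/M and mitosis 18 fell (median -0.77, adjusted p 0.00079), among them NUSAP1, a spindle protein, at -0.95, and CCNA2, cyclin A, at -1.05, while PLK1, a mitotic kinase, rose by 0.73. Of 26 proteasome subunits 18 fell (median -0.37, adjusted p 0.00145), with PSMD14 at -1.07 and PSMA4 at -0.89, and PSMB2 rose by 0.89. Of 16 YAP and TAZ targets 9 rose (median 0.73, adjusted p 0.0081), with CYR61 at 1.90, AJUBA at 1.61 and ARHGEF17 at 1.23. Of 26 matrix and mesenchymal genes 16 rose and 3 fell (median 0.61, adjusted p 0.0237); the collagens COL5A1 and COL4A2 rose by 1.35 and 0.78, and the integrin ITGB1 fell by 0.75. Of 31 cytosolic ribosomal proteins 21 fell and 6 rose (median -0.36, adjusted p 0.0237). The mitochondrial and ribosomal lists had been fixed as signs of RNA quality, and they passed in the same comparison as the immediate early, mitotic and proteasome lists. MT-ND6, PLK1 and PSMB2 were named after their values were seen.

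Counts adjusted over the list alone were the same as over all genes for these 7 lists. With an estimated correlation none of the 25 lists passed: the adjusted p was 0.725 for 6 of the 7 and 0.779 for ribosomal proteins. The call of the matrix list ended without wild-type piperlongumine replicate 2 (adjusted p 0.0948), and that of ribosomal proteins without wild-type DMSO replicate 2 (0.0752) or wild-type piperlongumine replicate 3 (0.0769). The other 18 lists had adjusted p from 0.0799 to 0.988.

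The change in wild-type cells followed GC content. In the tenth of genes lowest in GC the median change was log2 -0.75, and in the tenth highest it was 0.88; across 12347 genes, which are not independent replicates, the correlation of change with GC content was 0.744. The slope of expression on GC content, per 10% GC and relative to the mean library, averaged 0.37 ± 0.015 (SD, n = 3) in wild-type piperlongumine libraries and -0.21 ± 0.089 in wild-type DMSO libraries. That is a difference of 0.58, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 can give. The same difference was 0.13 for knockdown against wild-type cells under DMSO (exact permutation p 0.2), -0.46 under piperlongumine (exact p 0.1) and -0.0049 for piperlongumine in knockdown cells (exact p 0.9).

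**Figure D1:**
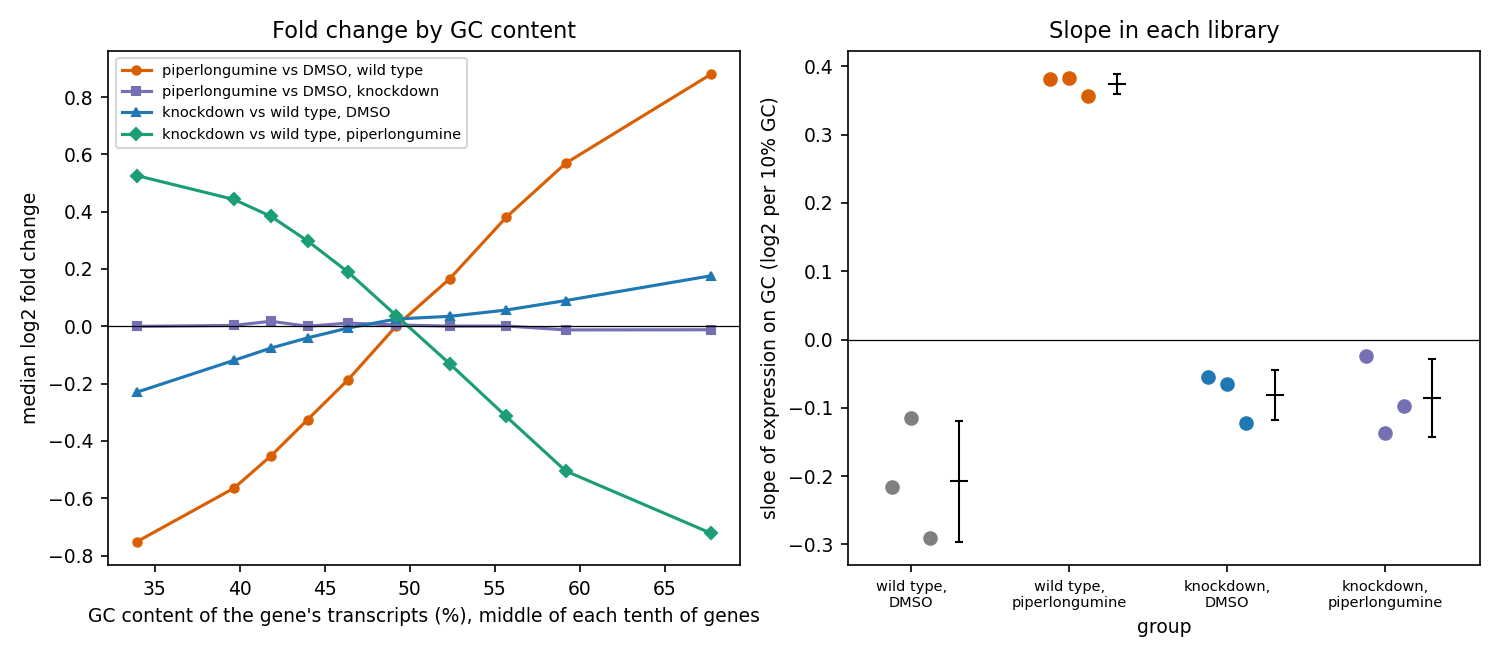
Median log2 fold change (vertical axis) of genes in 10 equal groups by GC content (horizontal axis, percent) for the 4 pairwise comparisons, and the slope of log2 expression per 10% GC content in each library, with group means ± SD (n = 3). The medians run from -0.75 to 0.88 for piperlongumine in wild-type cells and stay between -0.013 and 0.017 in knockdown cells.

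With GC content and length corrected, 4470 of 12347 genes were called in wild-type cells, 2090 higher and 2380 lower. Of the 7906 of those genes called without the correction, 3246 were called in the same direction with it and 148 in the opposite one. SPRY4 rose by log2 2.27, MT-ND1 by 2.86, MT-CYB by 2.83 and AJUBA by 1.35 after correction, and PI15 fell by 1.54, NDUFA5 by 1.22, TTK by 0.83 and PSMA1 by 0.65. Others kept their calls at smaller sizes, with IER2 at 0.75, COL5A1 at 0.54, ITGB1 at -0.25 and SNRPF at -0.84. The calls of PLK1 (corrected log2 0.24, adjusted p 0.0845), PSMD14 (-0.16, adjusted p 0.262), ARHGEF17 (0.29, adjusted p 0.141) and COL4A2 (-0.090, adjusted p 0.621) ended, and COL4A2 changed sign. The matrix list no longer passed camera (adjusted p 0.0748), while the immediate early, mitochondrial, mitotic, proteasome, YAP and TAZ and ribosomal lists did (largest adjusted p 0.0057), joined by NF-kB (0.0406) and DNA replication and G1/S (0.0444). With correction and an estimated correlation none passed (smallest adjusted p 0.629).

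**Figure D2:**
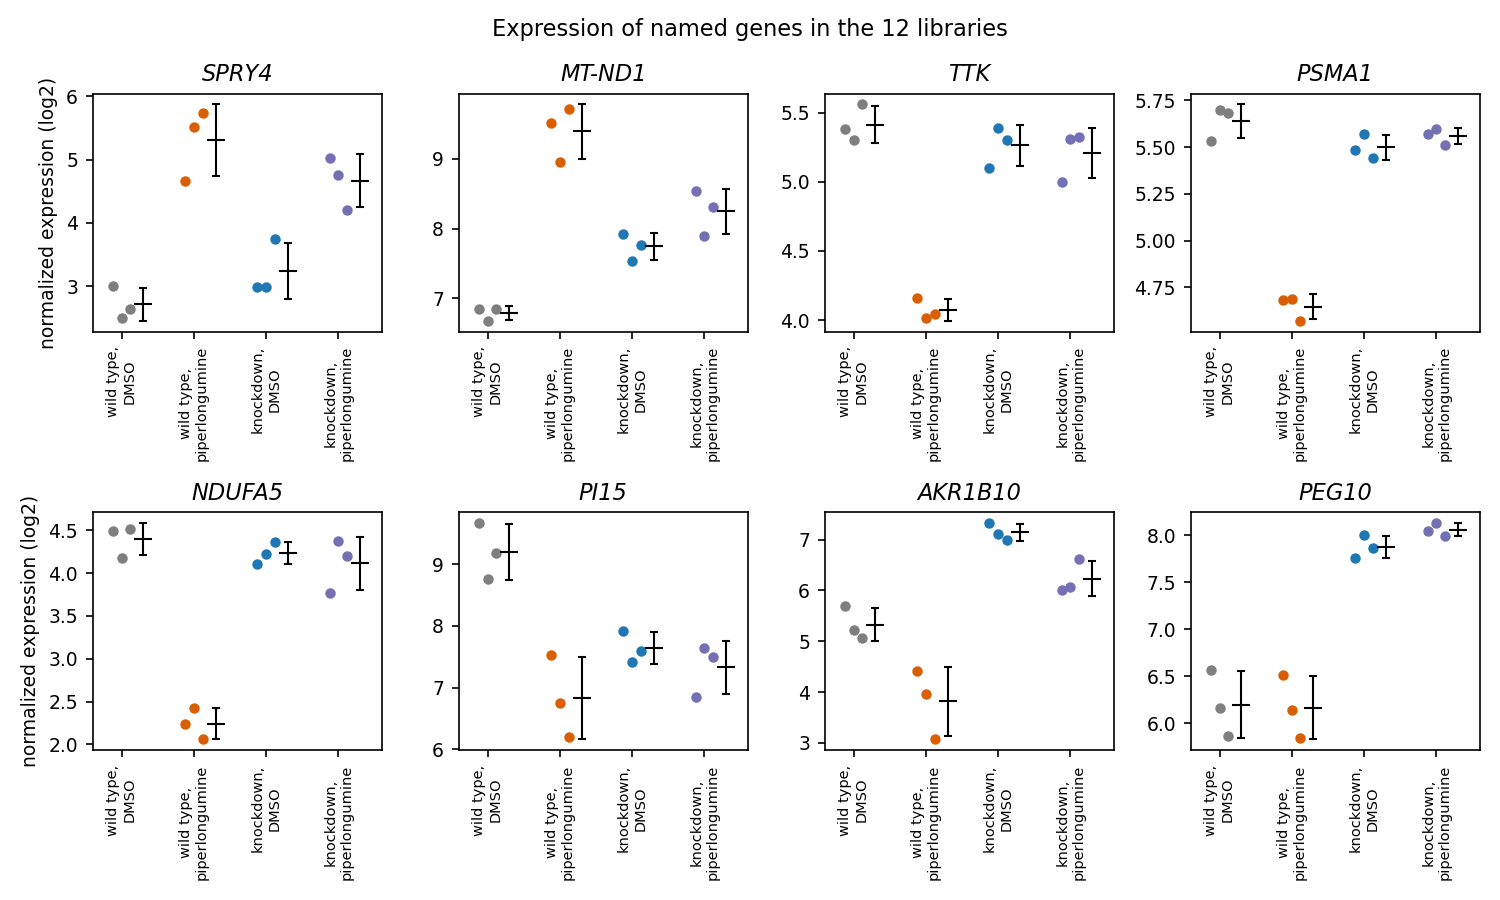
Log2 normalized expression (vertical axis) of 8 genes in each of the 12 libraries by group, with the mean and SD of 3 libraries. SPRY4 averaged 2.71 in wild-type DMSO, 5.30 in wild-type piperlongumine, 3.24 in knockdown DMSO and 4.67 in knockdown piperlongumine libraries.

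The second comparison asked what piperlongumine does to cells with TRPV2 knocked down. No single gene passed, so the values that follow are fitted log2 differences (n = 3 per group) and not called changes. SPRY4 was 1.34 ± 0.30 higher (SE, adjusted p 0.262), FOSL1, a component of the AP-1 transcription factor, 1.46 ± 0.36 (adjusted p 0.298), and DUSP4, a phosphatase of MAP kinases, 1.38 ± 0.39 (adjusted p 0.326). LIF, a cytokine, stood at 1.07 ± 0.24 (adjusted p 0.262) and THBS1, a matrix glycoprotein, at 1.02 ± 0.24 (adjusted p 0.283). AKR1C3, a reductase of the electrophile response, stood at -0.82 ± 0.19 (adjusted p 0.262).

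As groups, 9 of the 25 lists passed camera in knockdown cells, and none with an estimated correlation. The NF-kB list had a median of log2 0.64 over 10 genes (adjusted p 4.6e-07), with RELB and NFKB2, subunits of NF-kB, at 0.87 and 0.86. YAP and TAZ targets had 0.37 over 16 (adjusted p 2.6e-06), with CRIM1 at 0.57, CYR61 at 1.12 and AXL, a receptor kinase, at 0.93. For CYR61 the libraries of both groups overlapped. Immediate early genes had a median of 0.30 over 20 (adjusted p 4.6e-05), matrix genes 0.23 over 26 (adjusted p 0.00146), with LAMB1 at 0.42 and CDH2 at 0.39, and mitochondrial messages 0.30 over 13 (adjusted p 0.00146). The unfolded protein response had 0.095 over 19 (adjusted p 0.0221). The lists with negative medians were the NRF2 and electrophile response, at -0.25 over 21 genes (adjusted p 4.6e-07), with PGD and PIR at -0.57, glial and neural stem genes, at -0.38 over 18 (adjusted p 0.00167), and G2/M and mitosis, at -0.12 over 25 (adjusted p 0.00167), with KIF20A at -0.25, CENPF at -0.23 and BUB1B at -0.17. With an estimated correlation the adjusted p was 0.223 for NRF2, 0.255 for NF-kB, YAP and TAZ and glial genes, 0.468 for immediate early and matrix genes, 0.651 for mitochondrial and mitotic genes and 0.723 for the unfolded protein response.

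Over all genes limma called 0 of 13580 in knockdown cells, against 1144 at an unadjusted p under 0.05; the smallest adjusted p was 0.174. On simulated data, drawn with the same noise in every pairwise comparison, 30.6% to 45% of changes of log2 0.50 were found. Adjusted over the list alone, among the lists that passed, 7 NRF2 genes and 2 glial genes were lower, and 5 immediate early, 4 NF-kB, 1 YAP and TAZ and 1 matrix gene were higher. Among the other lists 2 integrated stress response genes, 1 p53 target and 1 calcium gene were higher, and 1 p53 target and 1 cytoskeletal gene lower. The 95% interval of the change lay within 2-fold for 13054 genes, 96.1%. With a replicate block 12 genes were called, 11 higher, with LIF (adjusted p 0.0101), FST, an activin antagonist, and FHL2 the smallest in p, and 1 lower, PTMAP2, a pseudogene (log2 -0.63); FST, FHL2 and PTMAP2 were named after their values were seen. Without knockdown piperlongumine replicate 3, 84 genes were called, among them FOSL1 (adjusted p 0.034) and DUSP4 (0.042) and also LIF, RELB, THBS1, AKR1C3, PGD, PIR and CRIM1. The mitotic list's call ended without knockdown DMSO replicate 2 (adjusted p 0.0872), the glial list's without knockdown DMSO replicate 3 (0.0781), and that of the unfolded protein response without knockdown DMSO replicate 1 (0.492), knockdown piperlongumine replicate 2 (0.184) or replicate 3 (0.11). The other 16 lists had adjusted p from 0.0968 to 0.724.

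The third comparison asked what the TRPV2 knockdown changes without the drug. Under DMSO, knockdown cells had higher levels of AKR1B10, PEG10 and PRRX1, and lower levels of CYCS, GJA1 and PI15. The calls of AKR1B10, GJA1 and PI15 ended in some fits with single libraries left out, and that of PI15 also with GC and length correction. AKR1B10, an aldo-keto reductase, was higher by log2 1.79 ± 0.30 (SE, n = 3 per group, adjusted p 0.0116), or 3.45-fold (chromosome 7, 134527592 to 134541408). PEG10, a gene derived from a retrotransposon, was higher by 1.66 ± 0.17 (adjusted p 0.00048; chromosome 7, 94656325 to 94669695), and PRRX1, a mesenchymal transcription factor, by 1.36 ± 0.17 (adjusted p 0.00072). CYCS, which encodes cytochrome c, was lower by log2 -0.96 ± 0.17 (adjusted p 0.0089), and GJA1, the gap junction protein connexin 43, by -0.86 ± 0.17 (adjusted p 0.0161).

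In all, 652 genes were called under DMSO, 401 higher and the others lower in knockdown cells, 38 of them at least 2-fold. The symbol CDR1-AS was higher by log2 2.01 ± 0.24 (adjusted p 0.00118); it matched no gene of the annotation, and the libraries do not tell it from transcripts of the opposite strand. EHD2, a membrane-shaping protein, was higher by 1.42 and MTCO1P12, a nuclear copy of mitochondrial sequence whose reads cannot be told from mitochondrial ones, by 1.41. PI15 was lower by -1.55, PRSS35 by -1.27, MTURN by -0.92 and TMED7, a carrier of the early secretory pathway, by -0.85. After the GC and length correction PI15 stood at log2 -1.24 (adjusted p 0.0708) and PRSS35 at -1.19 (0.079), past the threshold no longer. With single libraries left out the count was 219 without wild-type DMSO replicate 1, 109 without replicate 3, and 192, 137 and 208 without knockdown DMSO replicates 1, 2 and 3. AKR1B10 passed no longer without wild-type DMSO replicate 3 (adjusted p 0.063) or knockdown DMSO replicates 1 or 2 (0.051 each), and EHD2 without the same 3 (0.053 to 0.068). GJA1 (0.054 to 0.082), TMED7 (0.054 to 0.14) and PI15 (0.088 to 0.15) each passed, of the fits that left out 1 of the 6 libraries compared, only without wild-type DMSO replicate 2. MTURN failed without wild-type DMSO replicate 1 (0.11) or 3 (0.11) or knockdown DMSO replicate 2 (0.13) or 3 (0.086), and PRSS35 without any of the 6 libraries (0.077 to 0.18). The replicate block gave 1193 calls, and the fit without the 3 libraries with most tied values, 2 of them wild-type DMSO, gave 6.

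Of 13 mitochondrial messages, a list fixed as a sign of RNA quality, 6 were higher in knockdown cells under DMSO, with a median of log2 0.70 (camera adjusted p 2.0e-06, or 0.961 with an estimated correlation), led by MT-ND4 at 1.22 and MT-CYB at 1.20, while MT-ND6 was lower by -1.64. Adjusted over the list alone 10 were higher and 1 lower. Proteasome subunits had a median of -0.13 over 26 genes (adjusted p 0.0017, or 0.961 with an estimated correlation), and 1, PSMD14, was called lower (log2 -0.36), 2 adjusted over the list alone; PSMA5 at -0.39 (adjusted p 0.0531, or 0.0328 with the replicate block) and PSMA2 at -0.31 (0.0902) were not. Genes of cholesterol synthesis and uptake had a median of -0.21 over 22 (adjusted p 0.023, or 0.984 by the same test), and 1, STARD4, a carrier of cholesterol, was called lower (-0.95), 3 adjusted over the list alone; FDPS at -0.31 (adjusted p 0.0516, or 0.0222 with the block) and SQLE at -0.44 (0.0767) were not. The proteasome call ended with the GC and length correction and the replicate block together (adjusted p 0.0583), and PSMD14 then stood at log2 0.015. With the correction STARD4 stood at -0.64 and was not called (adjusted p 0.104). Of the fits that left out 1 of the 6 libraries, PSMD14 passed only without wild-type DMSO replicate 2 (0.063 to 0.13 otherwise), and STARD4 in none (0.051 to 0.14). The cholesterol list failed without wild-type DMSO replicate 1 (0.0892) or 2 (0.193) or knockdown DMSO replicate 2 (0.0508) or 3 (0.13). With the replicate block the NRF2 list (adjusted p 0.0442) and the matrix list (0.0202) also passed, and the 22 lists that did not pass without it had adjusted p from 0.0511 to 0.987. MT-ND4, MT-CYB and MT-ND6 were named here after their values were seen.

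Genes of chromosome 7 from 50 Mb to its end were higher in knockdown cells. Their median was log2 0.29 under DMSO over 398 genes with a GC value, 94 were called higher, and 23.6% were called higher against 2.39% on other autosomes. AKR1B10 and PEG10 lie there. Genes of chromosome 13 from 90 Mb were lower, with a median of -0.33 over 68 genes, 16 of them called lower. These values are without correction. With GC content and length corrected, the mean deviation of the chromosome 7 segment in single libraries was 0.095 to 0.171 in the 6 knockdown libraries. It was -0.177 to -0.124 in the 6 wild-type libraries. The chromosome 13 segment had -0.165 to -0.085 in knockdown and 0.110 to 0.166 in wild-type libraries, also corrected. With the correction and a replicate block, 1 of the windows of 10 Mb elsewhere passed 0.15 in both media. It lies on chromosome 19 from 50 Mb (160 genes, log2 0.20 under DMSO and 0.16 under piperlongumine). Both segments were chosen after the medians along the chromosomes were seen, so no test of them is given.

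**Figure D3:**
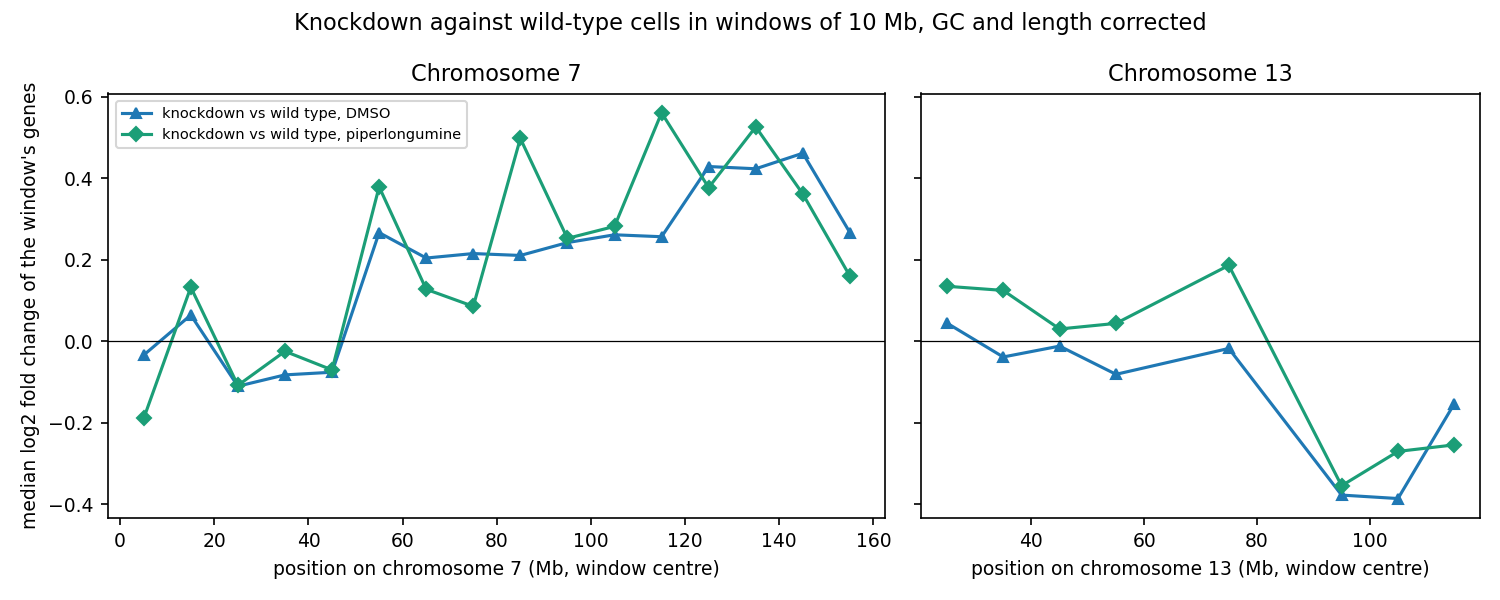
Median log2 difference, knockdown minus wild type (vertical axis), of genes in 10 Mb windows along chromosomes 7 and 13 (horizontal axis, Mb), under DMSO and under piperlongumine, with GC content and length corrected and a replicate block. All 11 windows of chromosome 7 from 50 Mb lie above 0 in both media, at 0.086 to 0.56, and the 3 windows of chromosome 13 from 90 Mb lie below 0 in both, at -0.39 to -0.15.

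The fourth comparison asked how knockdown and wild-type cells differ under piperlongumine. It shares the wild-type piperlongumine libraries with the first comparison, so what is particular to those libraries enters both, with opposite signs. It is therefore not separate evidence for lists that passed there. By list medians, genes of mitosis and of the proteasome stood higher in knockdown cells, and cholesterol genes, immediate early genes and mitochondrial messages lower. Of these, 11 of 22 cholesterol and 7 of 20 immediate early genes were called lower, where 3434 of all 13580 genes were lower and 55.4% were called either way. None of these lists passed with an estimated correlation (adjusted p 0.842 for each). TTK was higher by log2 1.09 ± 0.11 (SE, n = 3 per group, adjusted p 8.8e-06), PSMA1 by 0.89 ± 0.082 (adjusted p 6.9e-06) and NDUFA5 by 1.67 ± 0.15 (adjusted p 5.4e-06). AKR1B10 was higher by 2.33 ± 0.30 (adjusted p 0.00013), or 5.03-fold, PEG10 by 1.88 and PRRX1 by 1.69. SREBF2, the transcription factor that drives cholesterol synthesis, was lower by -1.07 ± 0.11 (adjusted p 8.3e-06).

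Under piperlongumine 7530 genes were called, 4096 higher and 3434 lower in knockdown cells. RPL22L1, a ribosomal protein paralog, was higher by log2 1.78 and CDH6, a cadherin, by 1.75. Among genes with a name, at or above the median abundance, without overlap between the groups, the largest falls were in SNORD3D, a symbol without a match in the annotation, at -3.62 ± 0.79 (adjusted p 0.0049), RN7SL4P at -1.79, RN7SKP203 at -1.63, RN7SKP255 at -1.61, JUND, a subunit of AP-1, at -1.59 and TTYH3, a membrane protein, at -1.56. RN7SL4P and both RN7SK pseudogenes are copies of abundant RNAs, so their reads cannot be told from those of the parent genes. How evenly the selection of polyadenylated RNA kept them, or SNORD3D, was not tested. RN7SL4P stood at -1.44 with the correction (adjusted p 0.0984) and also failed without wild-type piperlongumine replicate 2 (0.082) or 3 (0.1) or knockdown piperlongumine replicate 1 (0.083). The difference under piperlongumine correlated with GC content at -0.728 across genes, and GC and length correction left 3038 calls, 1607 higher and 1431 lower. With correction JUND stood at -0.74, TTYH3 at -0.75, SREBF2 at -0.63 and TTK at 0.72, all still called. AKR1B10 at 2.09 and PEG10 at 1.72 moved less.

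Of the 25 lists 6 passed camera under piperlongumine. Of 25 mitotic genes 17 were higher and 3 lower (median log2 0.54, adjusted p 0.0078), with BUB1, a checkpoint kinase, at 0.78 and KIF23, a cytokinesis motor, at 0.75. Of 26 proteasome subunits 15 were higher and 1 lower (0.27, adjusted p 0.0088), with PSMA6 at 0.90 and PSMD14 at 0.79. Of 22 cholesterol genes 11 were lower (-0.51, adjusted p 0.0096), with MVD, a mevalonate enzyme, at -1.60. Of 20 immediate early genes 7 were lower (-0.62, adjusted p 0.0096), with JUNB at -1.44, IER2 at -1.13 and NR4A1 at -1.0. Of 13 mitochondrial messages 8 were lower (-0.77, adjusted p 0.0132), and of 31 ribosomal proteins 19 were higher and 4 lower (0.36, adjusted p 0.0132). These last 2 lists are those of RNA quality. Adjusted over the list alone the counts were the same except for 20 ribosomal proteins higher.

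With an estimated correlation the adjusted p of these 6 lists was 0.842. The cholesterol call ended without knockdown piperlongumine replicate 1 (adjusted p 0.0566), the immediate early call without knockdown piperlongumine replicate 3 (0.0517) and the ribosomal call without wild-type piperlongumine replicate 3 (0.104). GC and length correction kept the 6 lists past the threshold (largest adjusted p 0.0101, but 0.848 for each with an estimated correlation), added DNA replication and G1/S (0.00497, or 0.848) and ended the calls of PSMD14 (corrected log2 0.24, adjusted p 0.104), IER2 (-0.53, 0.0985), NR4A1 (-0.44, 0.14) and JUNB (-0.79, 0.0742). The chromosome 7 segment had a median of 0.35 and the chromosome 13 segment one of -0.17 under piperlongumine, or 0.28 and -0.29 with correction and block. With the replicate block the list of DNA replication and G1/S also passed (adjusted p 0.0478), and without it the other 19 lists had adjusted p from 0.07 to 0.953.

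**Figure D4:**
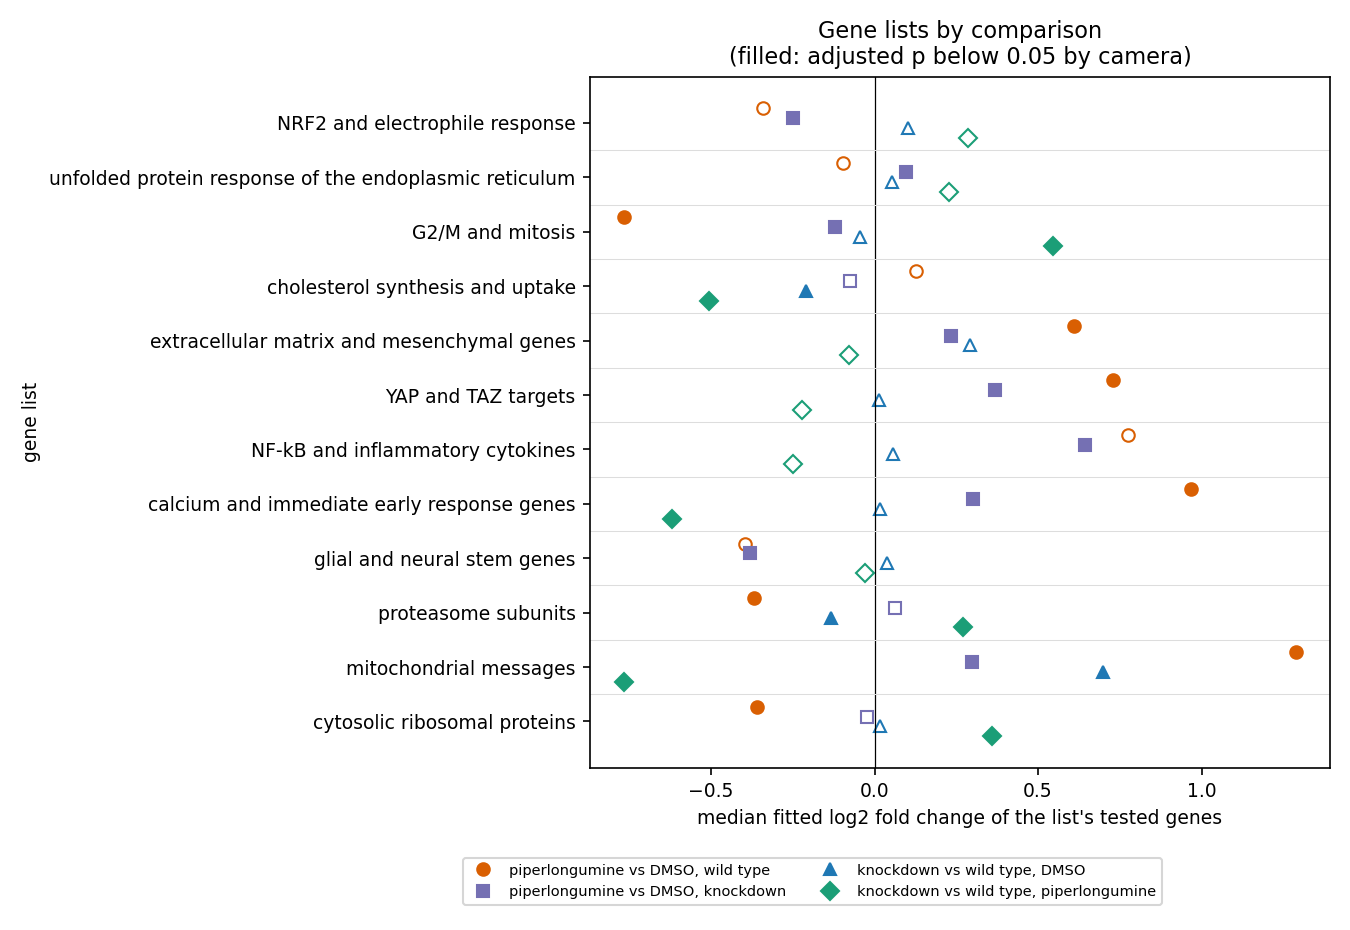
Median fitted log2 fold change (horizontal axis) of 12 gene lists (vertical axis) in the 4 pairwise comparisons, with filled points for lists with a camera adjusted p under 0.05 at the preset correlation. Mitochondrial messages lie at 1.29 for piperlongumine in wild-type cells, 0.30 in knockdown cells, 0.70 for knockdown under DMSO and -0.77 under piperlongumine.

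The interaction asked whether the response to piperlongumine differs between knockdown and wild-type cells. By list medians, mitochondrial messages responded less upward in knockdown cells, and proteasome and mitotic genes less downward, at a preset correlation between genes. Tested with an estimated correlation, none of them passed (adjusted p 0.871 for each). TWF1 differed by log2 1.92 ± 0.23 (SE, n = 3 per group, adjusted p 7.0e-05), NDUFA5 by 1.83 ± 0.21 (adjusted p 5.0e-05), and GMFB, a regulator of actin branching, by 1.71 ± 0.27 (adjusted p 0.00036). MT-CYB differed by -2.16 ± 0.28 (adjusted p 0.00017), PRR12 by -2.21 ± 0.23 (adjusted p 3.1e-05) and TTYH3 by -2.19 ± 0.24 (adjusted p 4.8e-05). These sizes are without correction: with GC and length corrected TWF1 stood at 1.29 and NDUFA5 at 1.10.

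In total 6237 genes were called for a different response, 3344 with a more positive and 2893 with a more negative response in knockdown cells. PI15 differed by log2 2.04 ± 0.50 (adjusted p 0.0088) and RN7SK by -3.52 ± 1.17 (adjusted p 0.0371), a size bounded by the common maximum that RN7SK held in 5 libraries. With GC and length correction 1564 genes were called, 776 more positive and 788 more negative, of which 1190 were among the 5777 called without it and in the same direction, and PI15 (corrected log2 1.23, adjusted p 0.114) and RN7SK (-3.07, adjusted p 0.116) were not called. RN7SK also failed without any one of 8 of the 12 libraries: wild-type DMSO replicates 2 and 3, wild-type piperlongumine 2 and 3, knockdown DMSO 2 and 3 and knockdown piperlongumine 1 and 2 (adjusted p 0.062 to 0.081). The proteasome list had a median of 0.40, with 14 of 26 more positive and 1 more negative (camera adjusted p 0.00054), and mitochondrial messages -1.06, with 9 of 13 more negative (adjusted p 0.00054). The mitotic list had 0.58, with 15 of 25 more positive and 1 more negative (adjusted p 0.0064), and immediate early genes -0.75, with 4 of 20 more negative (adjusted p 0.0283). Over all genes 2893 of 13580 were more negative, so the count of immediate early genes is near the share of all genes. Adjusted over the list alone 15 proteasome and 16 mitotic genes were more positive, with the other counts as given. With an estimated correlation the adjusted p of all 4 was 0.871. The immediate early call ended without wild-type DMSO replicate 2 (0.106) or 3 (0.0522), wild-type piperlongumine replicate 2 (0.0951), knockdown DMSO replicate 3 (0.0638) or knockdown piperlongumine replicate 3 (0.111), and the 21 other lists had adjusted p from 0.0715 to 0.989.

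The piperlongumine responses of both cell types correlated across genes at 0.233, with a slope of 0.075 of the knockdown response on the wild-type response. Of the genes called in wild-type cells, 58.2% had the same sign in knockdown cells, against 55.7% of all tested genes. With GC and length correction the correlation was 0.415 and the slope 0.21. The same sign was then held by 69.7% of called genes, against 62.4% of all genes with a GC value. The knockdown effect under DMSO correlated with the piperlongumine effect of wild-type cells at 0.530 across genes. These 2 effects share the wild-type DMSO libraries, and for that reason simulated groups without change gave a mean correlation of 0.464 when whole library profiles were drawn and 0.50 when genes were drawn independently. With GC and length correction the correlation was 0.349, against simulated means of 0.461 and 0.50. The simulated groups held noise alone, so their correlations are no baseline for effects that also hold real changes. Called higher in both were 294 genes, and lower in both 228, where independent calls would give 118 and 85.5. The shared libraries alone raise such counts, by how much was not tested. In opposite directions, 2 genes were higher with the drug and lower with the knockdown, and 40 were lower with the drug and higher with the knockdown.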

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

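Chosen only after the results were seen were the tests of GC content for the larger response of wild-type cells and for the chromosome segments, the test of a missing response, the test of copy number and the effects with no control library in common. A test of the difference itself singled out the results in the next 2 paragraphs: the response to piperlongumine differed between knockdown and wild-type cells.

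The response to piperlongumine was larger in wild-type cells, and limma called 6237 genes for the difference. A smooth trend on the GC content of the longest annotated transcript, as the whole cause, is argued against. With GC and length correction and a replicate block, 2245 genes, 18.2% of those with a GC value, still differed. Before correction the difference correlated with GC content at -0.773 across genes, and GC effects that the correction does not model stay open. Shallow wild-type libraries stay open as a cause. The fit without the 3 libraries with most tied values leaves 1 wild-type DMSO library, so its count of genes cannot decide. That the knockdown libraries under piperlongumine had no response at all stays open: with correction both responses correlated at 0.415 across genes, above the highest of the other relabellings, 0.326, but 20 relabellings cannot give a share under 0.05, and without correction 3 of 20 were as high as 0.233. With a replicate block 12 genes were called in knockdown cells, against 0 in the 3 other splits that part every pair of replicate numbers. Those splits are too few to decide. A weaker response because of the lost TRPV2 channel is a candidate explanation that was not tested apart from other differences between the 2 cell populations.

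In the same test PI15 differed by log2 2.04, TWF1 by 1.92, NDUFA5 by 1.83 and GMFB by 1.71, and RN7SK by -3.52, PRR12 by -2.21, TTYH3 by -2.19 and MT-CYB by -2.16. The list medians differed by 0.58 for G2/M and mitosis, 0.40 for proteasome subunits, -0.75 for calcium and immediate early response genes and -1.06 for mitochondrial messages, and no list held with an estimated correlation (adjusted p 0.871). Mitochondrial messages were fixed as a sign of RNA quality, and a difference in RNA quality between the libraries was not excluded. RN7SK held the common maximum in 5 libraries, which bounds its size, and RN7SK and PI15 were not called after GC and length correction (adjusted p 0.116 and 0.114).

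Relabelling cannot decide whether the number of genes called for the difference is beyond chance, since splits that keep the wild-type labels keep the wild-type response. Of 100 splits drawn from the 200 possible, 6 gave as many genes, the real one with 6237 included, and the highest other gave 6920. The 8 other drawn splits that kept the wild-type labels real gave 5790 to 6920 genes, 5 of them as many as the real one, and the 91 that did not gave 0 with limma, which points to the contrast within wild-type cells as the structure that carries the count. For the pairwise comparisons 10 splits are too few for a share under 0.05. There 1 of 10 splits was as large as the real one for piperlongumine in wild-type cells (8614 against a highest other of 0), 10 of 10 in knockdown cells (0 against 0), 1 of 10 for knockdown under DMSO (652 against 0) and 1 of 10 under piperlongumine (7530 against 6). Of the 9 others, 3 part all 3 pairs of replicate numbers, as the real one does, and gave 0 genes with limma, with and without the block; the other 6 part 1 pair and hold the highest count of 6.

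Knockdown cells had higher expression along chromosome 7 from 50 Mb to its end and lower expression along distal 13q, a pattern in data that no list or named-gene rule addressed. A trend on GC content is argued against, since with correction and block the medians under DMSO stayed at log2 0.29 and -0.32. A single library is argued against as well. With GC and length correction the lowest knockdown library had a mean deviation of 0.095 on the chromosome 7 segment, and the highest wild-type library one of -0.124. A difference in copy number between the 2 cell populations may account for it, but only with the correction: the corrected medians were 0.28 and -0.29 under piperlongumine, the rest of chromosomes 7 and 13 stayed between -0.060 and 0.071, and elsewhere 1 window, on chromosome 19 from 50 Mb, passed 0.15 in both media (0.20 and 0.16), while uncorrected the rest of 13 stood at 0.37 and distal 13q at -0.17 under piperlongumine. No DNA was measured and the segments were drawn after the windows were seen, so this is a hypothesis, and whether such a difference arose with the knockdown or by drift in culture was not tested.

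The effects of knockdown under DMSO and of piperlongumine in wild-type cells correlated at 0.530 across genes. Simulations of unchanged groups that share their controls, drawn as whole library profiles, averaged 0.464. They held noise alone, so their correlations are no baseline for effects that also hold real changes, and covariances were compared instead. The shared wild-type DMSO libraries were tested as the whole cause by the covariance: its value of 0.102 was above the highest of 100 such simulations, 0.0821, which argues against it. A trend on GC content remains a candidate explanation, since with correction the covariance, 0.0365, was below the highest simulated one, 0.0462, though above the simulated mean of 0.0139. That verdict rests on simulations that kept whole library profiles; simulations that drew genes independently reached at most 0.0202 without and 0.0174 with correction, and would have left the corrected value above. With no control library in common, in the 6 possible ways, the effects correlated at 0.234 to 0.507 without and 0.161 to 0.257 with correction, and 5 of 100 simulations reached the corrected mean covariance, 0 the uncorrected one.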

How the results depend on the processing

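The GC and length correction, alone and with the replicate block, the log2 values as deposited and the fit without the 3 libraries with most tied values were chosen after seeing the data. Quantile normalization, no filter, a mean of at least 5, a pseudocount of 0.1 and the values as deposited kept all 5 counts of called genes within 1.5 times, and no scaling moved the median of all genes by over 0.1. The deposited values already shared a near-common distribution and the filter left out only 8 genes, so quantile normalization and no filter could change little. Against a log2 change of 1 (treat), which tests for a larger change, 139 genes were called for piperlongumine in wild-type cells, 0 for knockdown under DMSO (11 at an unadjusted p under 0.05), 4 under piperlongumine and 3 for the interaction. The 4 are HIST1H3D (-3.48) and 3 with clone-based names, and the 3 are HIST1H3D (-3.47), ATN1 (-1.97) and 1 with a clone-based name, named after their values were seen. With GC and length correction the counts were 4470 for piperlongumine in wild-type cells, 432 and 3038 for knockdown under DMSO and piperlongumine, and 1564 for the interaction. With the block as well they were 5335 in wild-type cells, 12 in knockdown cells, 877 and 3925 for knockdown under DMSO and piperlongumine and 2245 for the interaction. Part of the calls followed GC content by the construction of the correction; why it differed between groups was not tested.

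The replicate block alone gave 12 genes for piperlongumine in knockdown cells and 1193 for knockdown under DMSO, where a fit of the compared groups alone gave 1206; the block changed no call of a named gene or list other than those given beside the results. Without the 3 libraries with most tied values, which leaves 1 wild-type DMSO library assumed to vary like the other groups, the counts were 5269 in wild-type cells, 6 for knockdown under DMSO and 3441 for the interaction, with fewer samples. Single libraries left out gave 109 to 860 genes for knockdown under DMSO (lowest without wild-type DMSO replicate 3), 0 to 84 for piperlongumine in knockdown cells (84 without knockdown piperlongumine replicate 3), 7601 to 8410 in wild-type cells, 6213 to 7379 for knockdown under piperlongumine and 5204 to 6384 for the interaction. The other counts of knockdown under DMSO were 219 and 860 without wild-type DMSO replicates 1 and 2, and 192, 137 and 208 without knockdown DMSO replicates 1, 2 and 3. Lists passing with an estimated correlation numbered 0 in all 5 contrasts; the cause was not tested. With fry 18 lists passed for piperlongumine in wild-type cells, 0 in knockdown cells, 0 for knockdown under DMSO and 12 under piperlongumine. Lists for knockdown under DMSO numbered 5 with the block, 6 without the 3 libraries and 3 to 5 with single libraries left out (5 without wild-type DMSO replicate 3), against 3; the cause was not tested. The correlation of piperlongumine and knockdown effects was 0.349 with correction and 0.336 without the 3 libraries, and that of both piperlongumine effects 0.415 with correction. COL4A2 reversed to -0.090 in wild-type cells and PSMD14 to 0.015 under DMSO with the correction, with and without block. Over all settings of named genes, the correction and treat included, 1450 results kept their side of the threshold. A change of sign was counted apart only where either fit passed the threshold. Another 155 fell short of it, 63 of them under treat, and 21 passed it. Alternatives that need counts were not run, since the values are not counts, and the estimated reads per value give no exact limit of depth.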

Other observations

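No test in this part was planned for the classes of small RNAs and histones, which were chosen after their values were seen, as were the single genes named here; the lists were fixed earlier. Lists that did not pass camera held genes that went both ways under piperlongumine in wild-type cells. Of 21 genes of the NRF2 and electrophile response 6 rose and 12 fell (13 adjusted over the list alone; median log2 -0.34, camera adjusted p 0.26). FTL and FTH1, the ferritin chains, rose by 1.10 and 0.59, and HMOX1, heme oxygenase, by 0.78. AKR1C3 and AKR1B10, aldo-keto reductases, fell by 1.55 and 1.44, GCLM and GCLC, the subunits of the glutathione synthesis enzyme, by 1.36 and 0.99, TXN, thioredoxin, by 0.98 and NQO1, a quinone reductase, by 0.56. Of 18 heat shock chaperones 2 rose and 8 fell (7 adjusted over the list alone; median -0.45, adjusted p 0.191), with HSPE1 and HSPD1, the mitochondrial chaperonins, at -1.57 and -0.93. BAG3, a cochaperone, and HSPB1, a small heat shock protein, rose by 0.53 and 0.64, but stood at 0.12 and -0.11 with GC and length correction and were not called.

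Of 23 genes of the integrated stress response 10 rose and 2 fell (median 0.30, adjusted p 0.0837). SLC3A2, an amino acid transporter chain, rose by 1.53, CHAC1, a glutathione-degrading enzyme, by 1.39 (0.70 with correction, adjusted p 0.0554) and SESN2 by 1.27, while MTHFD2, a mitochondrial folate enzyme, fell by 1.15. Of 19 p53 targets 8 rose and 5 fell (median 0.25, or -0.018 with correction, adjusted p 0.432), with CDKN1A, the cell cycle inhibitor p21, at 1.89 and FAS, a death receptor, at -1.07. Of 10 tested NF-kB genes 6 rose and 1 fell (median 0.77, adjusted p 0.0837, or 0.0406 with correction and 0.629 with correction and an estimated correlation), with RELB, a low gene whose change the pseudocount understates, at 1.86, NFKB2 at 1.68 and LIF at 1.52. Counts adjusted over the list alone were the same for these 3 lists. Of 22 genes of calcium channels and calcium handling 10 rose and 4 fell (median 0.086, adjusted p 0.432), also adjusted over the list alone, and for knockdown under DMSO 1 was higher (median 0.12, adjusted p 0.44).

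Classes of small RNAs and histones were counted without a test. Of 6 RN7SK pseudogenes 4 rose under piperlongumine in wild-type cells (median 1.23), and 4 were lower in knockdown cells under piperlongumine (median -1.09). Of 15 small nucleolar RNA genes 3 rose in wild-type cells, where 3987 of all 13580 genes rose. Of the same 15, 7 were lower in knockdown cells under piperlongumine (median -1.24). Of 12 small Cajal body RNA genes 2 rose and 5 fell in wild-type cells. Of 59 replication-dependent histone genes, whose messages mostly lack a poly(A) tail, 23 rose and 19 fell in wild-type cells (median -0.040), a share of called genes near that of all genes, and 5 were higher in knockdown cells under DMSO (median 0.29). COL1A2, a fibrillar collagen, was higher by 1.28 in knockdown cells under DMSO.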
